A study of Homo sapiens with 1072 samples.

How the data were processed

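The series holds 1072 human samples. Of these, 1060 are bulk RNA-seq libraries of cell populations sorted from solid tumours and 12 are single-cell libraries of myeloid cells sorted from tumours. Per the labels, the bulk populations were all viable cells, conventional T cells (CD4+ and CD8+ together), regulatory T cells (CD4+ CD25+), myeloid cells (HLA-DR+ and negative for T-cell, B-cell and NK-cell markers, with or without a CD11b gate), tumour cells (negative for CD45, CD90 and CD44, in some libraries also EPCAM+) and stroma. The 63 stroma samples were not used here. Per the labels' protocols, bulk cDNA was amplified from captured mRNA with the Ovation RNA-Seq kit and made into libraries with Nextera XT, and single cells were captured with the 10x Genomics 3' kit, which counts unique molecular identifiers (UMIs).

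The bulk tables hold TPM values as deposited by the authors. The submitters' processing notes name BWA and STAR without versions and the GRCh38 build for the bulk libraries. How TPM were computed from the alignments is not given in the sources used here. The tables of all viable cells and of myeloid cells have 57992 gene rows, and each library sums to 1000000 within rounding. The tables of both T-cell sorts and of tumour cells have 19918 rows, nearly all protein-coding, and their libraries sum to less, with medians of 667575 in conventional T cells, 667943 in regulatory T cells and 493234 in tumour cells. Rows without a gene symbol (829 of the longer tables and 259 of the shorter ones) held a median of 0.172% to 0.37% of the TPM per table and were left out. TPM keep no record of depth, so the sequencing depth of the bulk libraries is unknown, and the number of genes at a TPM of at least 1 is given in its place. The single-cell matrices hold whole-number counts of UMIs per gene and barcode as deposited. The submitters' processing notes name Cell Ranger without a version, Seurat 3 and GRCh38 for them.

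Columns were matched to samples by the specimen code in the labels. Of the value columns, 16 matched no sample of their compartment and were not used, 8 columns stand for 2 libraries with one label and were counted once, and 25 regulatory T-cell samples had no column. In all 964 libraries of 250 patients were used. Analyses were run on 19632 protein-coding symbols present once in every table, less Y-linked genes with their pseudoautosomal copies and the X-inactivation transcript, which left 19568 genes. Among the pseudoautosomal genes left out are IL3RA, CD99 and CSF2RA. Of the 19568 genes, 19196 have a place in GENCODE release 29 on GRCh38, and gene locations are 1-based and span the whole gene, exons and introns. Genes with close paralogs, such as FCGR3A, HSPA6, SFTPA1, SFTPA2 and KRT6A, are uncertain in so far as the authors' counting could split their reads.

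Bulk comparisons used limma 3.58.1 in R 4.3.3 with an intensity trend on log2(TPM + 1). Libraries of one patient were averaged, so the patient is the replicate. Fold changes on this scale understate the change of genes with low TPM. Genes entered a fit if they reached a TPM of 5 in enough patients for the smallest group. In each compartment a moderated F test compared 8 tumour types (bladder, colorectal, gynecologic, head and neck, kidney, lung, melanoma and sarcoma). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a range of type means of at least 1 log2. Each type was also set against the equal-weight mean of the other 7 types in the same fit, with a minimum difference of 1 log2. The gate was a covariate for myeloid and tumour cells. Types with too few patients were not compared. The type groups pool primary and metastatic specimens, and in viable cells 13 of 29 melanoma and 3 of 30 colorectal patients had metastatic ones. Regulatory and conventional T cells of the same patient were compared with the patient as a block, since the specimen label pairs them. Those libraries stand in separately made tables over the same gene rows with like sums. Metastatic and primary melanoma were compared without a minimum size.

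Gene lists, 40 in all, were tested with camera at its preset correlation of 0.01 and with the correlation estimated from the data, adjusted over the lists and types of a compartment. An adjusted p given for a list is the one with an estimated correlation unless the text says otherwise. The lists described were picked after their tests were seen, and not all called ones are given: at the preset correlation 106 of 264 list tests were called in viable, 87 of 208 in conventional T, 63 of 200 in regulatory T, 79 of 240 in myeloid and 92 of 168 in tumour cells, and 20, 15, 11, 9 and 21 with an estimated one. List medians are given relative to the median difference of all genes in the same contrast, and single genes as fitted. Across patients, 5 relations between list scores (mean log2 values of the members) were tested after centring on tumour type, with 100000 shuffles within types. The lists, tests, named-gene rule, cell-type markers and first set of alternatives were fixed before the data were examined. That plan counted 6 or more patients per type, and regulatory T cells of sarcoma had 5.

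Named genes are, for each type and compartment, the 2 called genes with the largest positive difference and, among called members of program lists that were higher, the one with the smallest adjusted p. For regulatory against conventional T cells they are the 10 largest rises and 10 largest falls that move the same way in at least 80% of pairs. For melanoma stage they are the 5 largest in each direction, and for a list described in the text up to 4 members with the smallest adjusted p. Genes of the sort gates are given in every compartment. T-cell receptor, immunoglobulin and mitochondrial genes were not named, and some genes that the rule takes are not reported here.

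Single cells were analysed with scanpy 1.11.5 in Python 3.11.15. Barcodes with at least 1000 UMIs, 500 genes and at most 20% mitochondrial UMIs were kept, which gave 42470 cells. Scrublet scores were used to remove 0.8% of cells per 1000 cells in a library as doublets, 2352 in all, leaving 40118 cells. The 2000 most variable genes, 30 principal components, a compact version of Harmony with 50 clusters, 15 neighbours and Leiden clustering at a resolution of 1.5 gave 29 clusters. A cluster was given a class name when at least 2 markers of the class stood among its 50 leading genes and at least 3 were detected, and otherwise stayed unnamed. The doublet share, the integration and the naming by leading genes were chosen after looking at the clusters, with 3 versions tried, and the versions set aside are among the alternatives. Libraries of one donor were added up. Class shares were compared by exact permutation over the 56 splits of 8 donors, and counts summed per donor over monocyte-like and macrophage-like cells were tested with edgeR 4.0.16 (TMM, quasi-likelihood), with DESeq2 1.42.0 as an alternative. The single-library lymph node and kidney samples are given as values. The head and neck and kidney matrices hold 737280 barcodes each and the melanoma matrices 449 to 6566, so how the authors filtered barcodes differed with tumour type.

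Tumour-type fits were tested on simulated data. With 200 genes raised by 1 log2 in kidney, 94% were recovered in all viable cells, 94% in conventional T cells, 82% in regulatory T cells, 96% in myeloid cells and 62% in tumour cells. Of genes changed by 2 log2 between melanoma stages, 64% were recovered in all viable cells, 55% in conventional T cells and 35% in myeloid cells. The paired T-cell fit recovered 100% of genes changed by 1.5 log2. In the single-cell fit 2% of genes changed 2-fold and 100% of those 8-fold were recovered.

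The alternatives were another pseudocount (0.1), no filter on low values, quantile normalisation, rescaling over the analysed genes, the number of detected genes as a covariate, leaving out the libraries with the fewest detected genes, leaving out metastatic specimens, each library as a replicate, single gates, and the way sample titles are written. Titles come in 3 styles, used here as a stand-in for library batch since the labels give no batch. No patient has libraries of several tumour types or both melanoma stages within a compartment. Among all 464166 pairs of libraries, 3 pairs from different patients correlated above 0.99, more closely than any other pair from different patients (0.976 at most) or from one patient (0.983). All 3 pairs join libraries labelled as different tumour types and 1 pair also different compartments, so labels or libraries in them are in doubt. They were kept, and every count was repeated without those 6 libraries. All 21 lung myeloid samples carry a source name that says bladder, and they were placed by their other labels.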

Results

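Cell populations sorted from human solid tumours were profiled by RNA-seq so that immune, tumour and unsorted cells could be compared across tumour types. In 5 sorted compartments 964 bulk libraries of 250 patients were used: 259 of all viable cells, 198 of conventional T cells, 157 of regulatory T cells, 188 of myeloid cells and 162 of tumour cells. The comparisons of 8 tumour types held 182 patients with conventional T cells, 146 with regulatory T cells, 172 with myeloid cells and 148 with tumour cells. With viable cells there were 14 patients with bladder, 30 with colorectal, 46 with gynecologic, 24 with head and neck, 49 with kidney and 33 with lung tumours. A further 29 had melanoma and 10 sarcoma. The smallest group was sarcoma among regulatory T cells, with 5 patients. Sequencing depth is unknown. A library had a median of 12209 detected genes (TPM of at least 1) in viable cells, 10976 in conventional T cells, 10516 in regulatory T cells, 10863 in myeloid cells and 11336 in tumour cells. The 12 single-cell libraries held 1293983 to 60842499 UMIs each.

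The sort gates were visible in the transcripts. CD3E, the T-cell receptor's signalling partner, had a median TPM of 535 in conventional and 553 in regulatory T cells against 1.2 in myeloid and 1.4 in tumour cells. FOXP3, the transcription factor of regulatory T cells, stood at 644.5 in regulatory and 27.2 in conventional T cells, and IL2RA (CD25) at 841 and 33. CD8A was at 307.5 in conventional and 8.2 in regulatory T cells, and CD4 at 71.8 and 216.2. Myeloid cells had the highest HLA-DRA (5290), ITGAM (126, the CD11b gene) and CD14 (116.5). Tumour cells had the highest EPCAM (54.8), and their PTPRC, the CD45 gene, was at 10.4 against 432 in viable cells. CD44 was at 189 in tumour cells and 641 in viable cells, and THY1 (CD90) at 0.4 in tumour cells and 3.5 in viable cells. These levels come from separately made tables and were not tested against one another.

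Viable cells carried the genes of the organ of origin. In colorectal tumours CEACAM5, the carcinoembryonic antigen, was higher than in the other 7 types by 6.16 ± 0.51 log2 (SE, n = 30) and LGALS4, a galectin of intestinal epithelium, by 5.47 ± 0.35. In bladder tumours the urothelial surface protein PSCA and the basal epithelial gene S100A2 were each higher by 5.48 (± 0.49 and ± 0.66). Gynecologic tumours were higher in WFDC2, a secreted protein of the female reproductive tract, by 5.27 ± 0.45 and in SCGB2A1 by 5.11 ± 0.31. Head and neck tumours were higher in the squamous keratins KRT14 (5.42 ± 0.33) and KRT6A (4.79 ± 0.39). Kidney tumours led in FXYD2, a sodium pump subunit (4.16 ± 0.22), and BHMT2 (3.31 ± 0.29), and lung tumours in the surfactant gene SFTPB (6.23 ± 0.38) and SCGB3A2 (5.32 ± 0.38). Melanoma led in the melanosome gene PMEL (3.70 ± 0.37) and sarcoma in the collagen gene COL1A2 (4.65 ± 0.76) and MFAP5 (4.49 ± 0.49). Among members of program lists, the smallest adjusted p went to PPARG in bladder (2.35 ± 0.34), CCL20 in colorectal (1.82 ± 0.35), IFI6 in gynecologic (1.06 ± 0.28) and CCR8 in head and neck (1.73 ± 0.36). The others were NDUFA4L2 in kidney (2.92 ± 0.31), LAMP3 in lung (1.27 ± 0.26) and FOLR2 in sarcoma (3.67 ± 0.53). The largest adjusted p among these genes was 0.00272, for IFI6, and 62.1% to 100% of a type's patients lay above the mean of the others.

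Organ lists were higher in their own type in viable cells. All 7 colon lineage genes were higher in colorectal (median 3.26 relative to all genes, adjusted p = 3.4e-16), and so were all 7 gynecologic (2.64, 1.01e-10) and all 6 squamous genes (3.56, 2.79e-17) in theirs. So were all 7 lung (4.07, 1.94e-13) and all 8 melanocyte genes (3.16, 1.48e-05), with 5 of 6 kidney genes (1.89, 2.35e-05) and 4 of 5 urothelial genes in bladder (2.36, 1.85e-10). Adjusted over the list alone, these counts were the same except for 5 of 5 urothelial genes. In sarcoma all 9 fibroblast genes were higher, over all genes and adjusted over the list alone (3.39, adjusted p = 0.00208). They were joined by 9 of 11 complement-high macrophage genes by both counts (2.29, 0.0312), among them SELENOP (3.04 ± 0.54) and LYVE1 (2.07 ± 0.41).

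Immune lists also differed between types in viable cells. Kidney tumours had 14 of 15 cytotoxic effector genes higher by both counts (median 1.45 relative to all genes; adjusted p = 1.33e-10, and adjusted p = 0.144 with an estimated correlation), such as the Fc receptor gene FCGR3A (2.57 ± 0.28), the granule gene NKG7 (2.29 ± 0.34), FGFBP2 (2.19 ± 0.23) and the cytokine IFNG (1.80 ± 0.28). Of the complement-high macrophage genes 8 of 11 were higher in kidney by both counts (1.21; adjusted p = 0.000573, and adjusted p = 0.408 with an estimated correlation), such as APOE (2.28 ± 0.35) and C1QB (2.09 ± 0.36). Fibroblast genes were lower in kidney, 7 of 9 by both counts (-2.04, adjusted p = 0.0472), including LUM (-2.33 ± 0.35) and COL1A1 (-2.06 ± 0.31). Head and neck tumours were higher in regulatory T-cell genes, 4 of 15 over all genes and 9 adjusted over the list alone (1.01, adjusted p = 0.0253), FOXP3 by 1.46 ± 0.37 and CD177 by 1.35 ± 0.35. LAMP3 dendritic-cell genes passed for 2 of 8 in head and neck, 3 adjusted over the list alone (0.85, adjusted p = 0.00338), and for 4 of 8 in lung by both counts (0.74; adjusted p = 0.018, and adjusted p = 0.388 with an estimated correlation). In colorectal tumours 2 of 6 plasma-cell genes were higher by both counts (1.25, adjusted p = 0.0472), JCHAIN by 2.90 ± 0.57. In bladder the alveolar macrophage list passed (1.48, adjusted p = 0.0289), with 1 of 5 members higher, 3 adjusted over the list alone. That member, PPARG, is also a transcription factor of urothelium. Melanoma was lower in 6 of 7 mast-cell genes by both counts (-1.22; adjusted p = 5.07e-08, and adjusted p = 0.0676 with an estimated correlation), the tryptase TPSAB1 by -3.89 ± 0.50. It was lower in 7 of 8 inflammatory cytokine genes by both counts (-1.94; adjusted p = 5.31e-06, and adjusted p = 0.146 with an estimated correlation), CCL20 by -2.09 ± 0.35. Without the 13 metastatic patients among the 29 with melanoma, 1 cytokine gene was lower, 3 adjusted over the list alone (adjusted p = 0.00605, and adjusted p = 0.492 with an estimated correlation).

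The moderated F test of limma called 6519 of 14022 genes across the 8 types in viable cells, and 6534 with the title style as a term. The median difference of all genes was -0.34 in colorectal, 0.19 in kidney, -0.15 in melanoma and 0.19 in sarcoma, and between -0.04 and 0.01 over all types after quantile normalisation. No list described here changed sign under either scaling. Mitochondrial genes held a median of 38.03% of the TPM in colorectal and 17.6% in kidney libraries. On GRCh38, CEACAM5 lies on chromosome 19 from 41708585 to 41729798 and SFTPB on chromosome 2 from 85657314 to 85668741. PMEL lies on chromosome 12 from 55954105 to 55973317.

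Conventional T cells of colorectal tumours had a type 17 profile. Of 8 type 17 genes tested, 7 were higher in colorectal T cells by both counts (n = 24; median 1.47 relative to all genes, adjusted p = 4.73e-08). They included the cytokines IL17A (2.20 ± 0.25) and IL26 (1.42 ± 0.26), the cytokine receptor IL23R (1.02 ± 0.18) and the chemokine CCL20 (1.85 ± 0.34). In the same libraries epithelial genes were higher for 4 of 7, 5 adjusted over the list alone (adjusted p = 0.0165), and plasma-cell genes for 1 of 5 by both counts (adjusted p = 0.00307, and adjusted p = 0.141 with an estimated correlation). As a list, complement-high macrophage genes were lower, 0 of 10 over all genes and 2 adjusted over the list alone (adjusted p = 0.000107, and adjusted p = 0.208 with an estimated correlation). In melanoma (n = 22) the type 17 list was lower, with 2 of 8 genes by both counts (-0.78, adjusted p = 0.0363), CCL20 by -1.77 ± 0.35. Tissue-resident genes were lower there as well, 3 of 8 by both counts (-0.76, adjusted p = 0.0239): the chemokine receptor CXCR6 (-1.60 ± 0.29), the integrin ITGA1 (-1.30 ± 0.27) and the transcription factor ZNF683 (-1.74 ± 0.39). In the same melanoma libraries 3 of 14 immediate-early and heat-shock genes, a sign of handling and RNA quality, were lower, 6 adjusted over the list alone (adjusted p = 0.000384, and adjusted p = 0.368 with an estimated correlation). So were 3 of 10 complement-high macrophage genes, 5 adjusted over the list alone (adjusted p = 2.97e-05, and adjusted p = 0.17 with an estimated correlation), and 2 of 8 monocyte genes, 4 adjusted over the list alone (adjusted p = 0.000981, and adjusted p = 0.246 with an estimated correlation). Epithelial genes were lower for 4 of 7, 6 adjusted over the list alone (adjusted p = 1.02e-06, and adjusted p = 0.116 with an estimated correlation). By both counts 1 of 8 fibroblast genes was lower (adjusted p = 1e-04, and adjusted p = 0.178 with an estimated correlation) and 1 of 5 B-cell genes higher (adjusted p = 0.0031, and adjusted p = 0.168 with an estimated correlation). These melanoma T cells pooled 8 metastatic and 14 primary patients, and the lists changed without the metastatic specimens. Of the type 17 genes 1 was then lower, CCR6 (-1.36), and 2 adjusted over the list alone (adjusted p = 1.28e-05, and adjusted p = 0.0847 with an estimated correlation), with CCL20 standing at -1.31 (adjusted p = 0.193). Of the tissue-resident genes 0 passed by either count (adjusted p = 0.00367, and adjusted p = 0.249 with an estimated correlation), CXCR6 standing at -0.81 (adjusted p = 0.381), ITGA1 at -0.71 (0.447) and ZNF683 at -0.74 (0.647). Over all genes 0 immediate-early and heat-shock, complement-high macrophage, monocyte, epithelial, fibroblast and B-cell genes passed, with 1, 0, 1, 6, 0 and 0 adjusted over the list alone (adjusted p = 0.387, 0.421, 0.421, 0.117, 0.421 and 0.627 with an estimated correlation).

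Cytotoxic genes differed between types in conventional T cells. In kidney (n = 42), 5 of 15 were higher by both counts (median 0.62 relative to all genes; adjusted p = 3.8e-06, and adjusted p = 0.17 with an estimated correlation), FCGR3A by 1.91 ± 0.28, FGFBP2 by 1.62 ± 0.32 and NKG7 by 1.30 ± 0.25. Beside them 4 of 10 complement-high macrophage genes were higher in the kidney T-cell libraries by both counts (0.67; adjusted p = 0.0105, and adjusted p = 0.388 with an estimated correlation), such as APOE (2.01 ± 0.31) and C1QB (1.65 ± 0.38). The heat-shock gene HSPA6 was higher too (2.81 ± 0.54). In the immediate-early and heat-shock list, which does not hold HSPA6, 4 of 14 genes were higher by both counts (adjusted p = 0.0223, and adjusted p = 0.54 with an estimated correlation). In lung (n = 23), 7 of 15 cytotoxic genes were lower, 8 adjusted over the list alone (-0.88; adjusted p = 2.6e-07, and adjusted p = 0.137 with an estimated correlation), NKG7 by -1.77 ± 0.31 and GZMH by -1.76 ± 0.38. In melanoma 4 of 15 were lower, 6 adjusted over the list alone (adjusted p = 2.06e-07, and adjusted p = 0.134 with an estimated correlation), but 0 by either count without metastatic specimens (adjusted p = 0.43, and adjusted p = 0.777 with an estimated correlation). The lung T cells were also lower in 5 of 10 proliferation genes by both counts (-0.93; adjusted p = 8.79e-05, and adjusted p = 0.239 with an estimated correlation), CCNA2 by -1.71 ± 0.27 and MKI67 by -1.20 ± 0.31. They were higher in the lymph-node homing receptor CCR7 (1.46 ± 0.36) and in IQCN (2.92 ± 0.32). Beside these, 2 of 8 fibroblast genes were lower (adjusted p = 0.000981, and adjusted p = 0.258 with an estimated correlation) and 1 of 8 monocyte genes higher (adjusted p = 0.0149, and adjusted p = 0.388 with an estimated correlation), each by both counts. In sarcoma (n = 8) naive and central memory genes were lower, with 1 of 9 over all genes, CCR7 (-2.25 ± 0.57), and 7 adjusted over the list alone (-1.30, adjusted p = 0.0068). Of the cytotoxic genes 1 of 15 was higher there, CST7 (1.30 ± 0.32), and 5 adjusted over the list alone (adjusted p = 5.89e-07, and adjusted p = 0.142 with an estimated correlation). In the same sarcoma libraries immediate-early and heat-shock genes were lower as a list, with 0 of 14 by either count (adjusted p = 9.23e-06, and adjusted p = 0.242 with an estimated correlation). Epithelial genes were lower as a list, 0 of 7 over all genes and 6 adjusted over the list alone (adjusted p = 3.48e-08, and adjusted p = 0.057 with an estimated correlation). Complement-high macrophage genes were higher as a list, 0 of 10 over all genes and 1 adjusted over the list alone (adjusted p = 0.00168, and adjusted p = 0.298 with an estimated correlation). In head and neck (n = 16) the tissue-resident list (0.65, adjusted p = 0.0363) and the regulatory list (0.87, adjusted p = 0.0286) passed, each with 1 member over all genes, RGS1 (1.03 ± 0.23) of 8 and FOXP3 (1.46 ± 0.37) of 15, and with 2 and 4 adjusted over the list alone. Lower as lists in the same libraries were complement-high macrophage genes, 0 of 10 over all genes and 2 adjusted over the list alone (adjusted p = 0.00292, and adjusted p = 0.33 with an estimated correlation), and monocyte genes, 0 of 8 and 1 (adjusted p = 0.0137, and adjusted p = 0.388 with an estimated correlation). There the survival receptor IL7R was higher in 100% of patients (1.24 ± 0.28), with DKK3 (2.54 ± 0.46) and CH25H (1.94 ± 0.49). ZNF683 was higher in gynecologic (1.39 ± 0.32) and the interferon-induced IFIT2 in bladder T cells (1.65 ± 0.39; adjusted p = 0.0545 without metastatic specimens of other types).

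Genes of the tumour's own tissue were measured in the T-cell libraries too. CEACAM5 was higher in colorectal T cells by 4.15 ± 0.41 and LGALS4 by 3.27 ± 0.31. WFDC2 and SCGB2A1 were higher in gynecologic T cells (3.89 ± 0.41 and 2.54 ± 0.21), and PSCA and S100A2 in bladder (3.37 ± 0.32 and 3.35 ± 0.58). SFTPB was higher in lung (3.66 ± 0.36), FXYD2 in kidney (2.91 ± 0.26) and PMEL and TYRP1 in melanoma (2.89 ± 0.33 and 2.33 ± 0.29). In sarcoma it was FSTL1 and COL1A2 (3.71 ± 0.63 and 3.47 ± 0.57). By both counts 7 of 7 melanocyte genes (median 2.06 relative to all genes, adjusted p = 2.19e-10), 5 of 5 lung (2.77, 1.6e-07) and 3 of 5 colon genes (1.73, 1.3e-11) were higher in their own type. So were 3 of 5 squamous (1.44, 0.000397), 3 of 6 kidney (0.83, 0.0176), 2 of 3 gynecologic (1.55, 1.72e-10) and, in sarcoma, 8 of 8 fibroblast genes (2.08, 1.07e-07). In bladder the urothelial list did not pass, with 0 of 3 genes by either count (adjusted p = 0.0524, and adjusted p = 0.17 with an estimated correlation).

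In conventional T cells limma called 2453 of 12600 genes across types, and 2297 with the title style as a term. Among the genes named by rule the largest adjusted p was 0.0435, for CH25H, and 59.1% to 100% of patients lay above the mean of the others. The median of all genes was 0.18 in kidney, -0.15 in lung and -0.11 in colorectal and between -0.04 and 0.02 after quantile normalisation, which turned the sign of no list described here. IL17A lies on chromosome 6 from 52186375 to 52190638, IL26 on chromosome 12 from 68201351 to 68225821. FCGR3A lies on chromosome 1 from 161541759 to 161550737 and CCR7 on chromosome 17 from 40553769 to 40565472.

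Regulatory T cells of colorectal tumours were also higher in type 17 genes, 4 of 9 by both counts (n = 21; median 1.18 relative to all genes, adjusted p = 4.81e-08), with IL26 (1.35 ± 0.23), KLRB1 (1.40 ± 0.31) and IL23R (1.13 ± 0.25). Complement-high macrophage genes were lower in these libraries for 4 of 11, 7 adjusted over the list alone (adjusted p = 7.97e-07, and adjusted p = 0.144 with an estimated correlation). In melanoma (n = 15) the regulatory list was lower, 5 of 15 genes over all genes and 8 adjusted over the list alone (-1.03; adjusted p = 6.26e-10, and adjusted p = 0.198 with an estimated correlation): CD177 by -3.22 ± 0.50, CCR8 by -1.94 ± 0.45, the decoy receptor IL1R2 by -1.75 ± 0.45 and the ectonucleotidase ENTPD1 by -1.55 ± 0.35. In the same libraries 3 of 14 immediate-early and heat-shock genes were lower, 5 adjusted over the list alone (adjusted p = 0.000555, and adjusted p = 0.465 with an estimated correlation). Complement-high macrophage genes were lower there for 3 of 11, 6 adjusted over the list alone (adjusted p = 9.45e-05, and adjusted p = 0.299 with an estimated correlation). Naive and central memory genes passed as a list in melanoma (0.92, adjusted p = 0.0167), with TCF7, a transcription factor of naive and memory T cells, higher by 1.88 ± 0.36 as the 1 of 9 members over all genes and 4 adjusted over the list alone. The melanoma group here pooled 6 metastatic and 9 primary patients. With the primary ones alone 0 of 9 naive and central memory genes passed by either count (adjusted p = 0.101, and adjusted p = 0.584 with an estimated correlation), TCF7 standing at 1.03 (adjusted p = 0.446). Of the regulatory list 1 of 15 was then lower, CD177, and 3 adjusted over the list alone (adjusted p = 7.68e-06, and adjusted p = 0.364 with an estimated correlation), with CCR8 at -1.92 (adjusted p = 0.129), IL1R2 at -1.77 (0.227) and ENTPD1 at -0.91 (0.477). Of the immediate-early and complement-high genes 0 passed over all genes, and 0 and 3 adjusted over the list alone (adjusted p = 0.534 and 0.437 with an estimated correlation). In kidney (n = 35) the complement gene C3 was higher by 3.48 ± 0.46, HSPA6 by 2.81 ± 0.52 and FCGR3A by 2.42 ± 0.36. Immediate-early and heat-shock genes as a list were higher for 5 of 14, 6 adjusted over the list alone (adjusted p = 0.000598, and adjusted p = 0.465 with an estimated correlation). Complement-high macrophage genes were higher beside them, 6 of 11 by both counts (1.07; adjusted p = 9.6e-07, and adjusted p = 0.146 with an estimated correlation), with APOE (2.21 ± 0.37) and C1QB (2.24 ± 0.45). In sarcoma (n = 5) RNASE1 (4.2 ± 1.07), CAV1 (4.03 ± 0.76) and SELENOP (3.60 ± 0.84) were higher. RNASE1 lost its call without patient 1, 2, 4 or 5 (adjusted p = 0.0922, 0.208, 0.427 and 0.191) and without metastatic specimens of other types (0.0703), SELENOP without patient 2, 4 or 5 (adjusted p = 0.119, 0.348 and 0.0844) and CAV1 without patient 5 (adjusted p = 0.127). Lower as lists in these sarcoma libraries were immediate-early and heat-shock genes, with 0 of 14 by either count (adjusted p = 6.45e-05, and adjusted p = 0.387 with an estimated correlation), and epithelial genes, with 0 of 7 by either count (adjusted p = 2.12e-05, and adjusted p = 0.19 with an estimated correlation). SELENOP was the 1 of 11 complement-high genes to pass there, with 6 adjusted over the list alone (1.87, adjusted p = 0.0449). Of 9 fibroblast genes 5 passed, 9 adjusted over the list alone (1.93, adjusted p = 2.17e-05).

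Tissue genes were likewise higher in the regulatory T cells of their own type. PSCA was higher in bladder by 4.07 ± 0.46 and KRT7 by 3.02 ± 0.64, and CEACAM5 and LGALS4 in colorectal (3.20 ± 0.40 and 2.49 ± 0.34). WFDC2 and PPP1R2C led in gynecologic (3.84 ± 0.46 and 2.36 ± 0.50) and KRT5 and KRT6A in head and neck (2.56 ± 0.44 and 2.26 ± 0.41). SFTPB and SFTPA2 led in lung (3.96 ± 0.33 and 3.03 ± 0.31) and DCT in melanoma (2.23 ± 0.35). The lists passed for 6 of 6 lung (median 2.17 relative to all genes, adjusted p = 2.17e-10), 4 of 6 melanocyte (1.72, 0.000227) and 3 of 5 colon genes (1.41, 2.89e-08). They also passed for 3 of 5 squamous (1.58, 0.000406), 2 of 5 gynecologic (0.98, 8.15e-09) and 2 of 6 kidney genes (0.79, 0.0081), with the same counts adjusted over the list alone except for 4 squamous genes. The urothelial list did not pass in bladder, with 0 of 4 genes over all genes and 1 adjusted over the list alone (adjusted p = 0.158, and adjusted p = 0.465 with an estimated correlation). Across types limma called 1156 of 12985 genes, and 988 with the title style as a term. The largest adjusted p among the genes named by rule was 0.0417, for RNASE1, and 63.2% to 100% of patients lay above the mean of the others. The median of all genes was -0.21 in colorectal, -0.16 in melanoma and 0.13 in sarcoma and between -0.02 and 0.00 after quantile normalisation, and no list described here changed sign. C3 lies on chromosome 19 from 6677704 to 6730562.

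**Figure D1:**
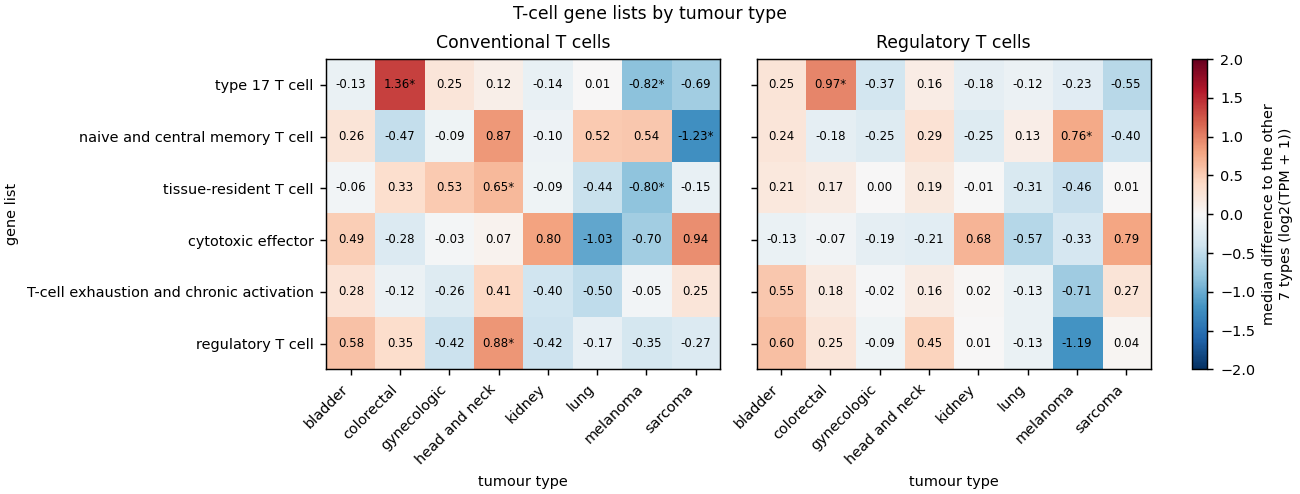
Median difference of 6 T-cell gene lists (rows) between each of 8 tumour types (columns) and the mean of the other 7, in log2(TPM + 1) and not relative to all genes, for conventional and for regulatory T cells; an asterisk marks an adjusted p under 0.05 with an estimated correlation. The type 17 list stands at 1.37 in conventional and 0.97 in regulatory T cells of colorectal tumours.

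Myeloid cells differed by type in macrophage, dendritic-cell and cytokine genes. Kidney myeloid cells (n = 40) were higher in C3 by 2.63 ± 0.35 and in the lipid carrier APOE by 2.07 ± 0.37. They were lower in 5 of 8 inflammatory cytokine genes by both counts (median -1.64 relative to all genes; adjusted p = 1.97e-08, and adjusted p = 0.12 with an estimated correlation), CXCL8 by -1.87 ± 0.37, CCL20 by -1.97 ± 0.39, IL1A by -1.99 ± 0.40 and IL6 by -2.10 ± 0.47. Of the LAMP3 dendritic-cell genes 4 of 8 were lower by both counts (-1.10; adjusted p = 9.76e-06, and adjusted p = 0.0754 with an estimated correlation), LAMP3 by -1.11 ± 0.28 and CCR7 by -1.26 ± 0.36. Epithelial genes were lower in the same kidney libraries, 4 of 7 by both counts (adjusted p = 5.08e-07, and adjusted p = 0.136 with an estimated correlation). Head and neck (n = 17) went the other way for the cytokines: no member passed over all genes, 7 of 8 passed adjusted over the list alone and the list passed (1.70, adjusted p = 0.0148), IL1A standing at 2.14 ± 0.56 (adjusted p = 0.0572). The elastase MMP12 was higher there by 2.61 ± 0.52.

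Lung myeloid cells (n = 20) were higher in the chemokine CCL17 (2.98 ± 0.54) and in 3 of 5 genes of type 2 conventional dendritic cells, 4 adjusted over the list alone (median 1.48 relative to all genes): the Langerin gene CD207 (2.29 ± 0.50) and the lipid-antigen presenters CD1E (2.28 ± 0.51) and CD1C (1.52 ± 0.44). Monocyte genes were lower, 4 of 8 over all genes and 5 adjusted over the list alone (-1.08), S100A12 by -1.86 ± 0.54 and CD14 by -1.09 ± 0.33. Both calls were made at the preset correlation (adjusted p = 9.12e-05 and 7.11e-06) and lost otherwise (each adjusted p = 0.163 with an estimated correlation). In melanoma (n = 18) SPP1-type macrophage genes were lower, 3 of 8 over all genes and 5 adjusted over the list alone (-1.24; adjusted p = 0.000162, and adjusted p = 0.182 with an estimated correlation), FN1 by -2.24 ± 0.54 and TREM2 by -1.74 ± 0.44. Without the 6 metastatic of these 18 patients 0 of 8 passed by either count (adjusted p = 0.99, and adjusted p = 1 with an estimated correlation), FN1 standing at -1.07 (adjusted p = 0.369) and TREM2 at -0.87 (0.389). In the melanoma libraries 4 of 7 epithelial genes were lower (1 without metastatic patients), 6 adjusted over the list alone (adjusted p = 1.59e-07, and adjusted p = 0.12 with an estimated correlation). ADM, a hypoxia-induced peptide hormone, was higher in bladder (1.93 ± 0.47) and colorectal (1.10 ± 0.30), and CADM1, an adhesion molecule of type 1 dendritic cells and epithelium, in gynecologic myeloid cells (2.21 ± 0.34).

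Tissue genes followed the type in myeloid libraries as well. PSCA (4.28 ± 0.40) and KRT13 (4.25 ± 0.37) were higher in bladder and CEACAM5 (4.37 ± 0.49) and LGALS4 (3.57 ± 0.31) in colorectal. WFDC2 (4.33 ± 0.38) and SCGB2A1 (3.01 ± 0.25) were higher in gynecologic, KRT5 (2.56 ± 0.48) in head and neck and SFTPB (3.96 ± 0.30) in lung. TYRP1 (2.28 ± 0.27) and PMEL (1.91 ± 0.33) were higher in melanoma, and CAV1 (3.01 ± 0.63) and COL6A2 (2.92 ± 0.49) in sarcoma. By list, 4 of 4 colon (median 2.18 relative to all genes, adjusted p = 9.35e-11), 4 of 4 lung genes (2.49, 3.7e-09) were higher in their own type. So were 4 of 5 squamous (2.33, 1.21e-08), 4 of 5 gynecologic (1.24, 1.42e-08) and 4 of 6 melanocyte genes (1.67, 6.22e-07), and 3 of 7 general epithelial genes in bladder (1.75, 0.0289). Adjusted over the list alone these counts were the same except for 5 squamous and 6 epithelial genes. In myeloid cells limma called 3494 of 12514 genes, and 3424 with the title style as a term. With the CD11b-gated libraries alone 2111 were called, of which 1798 were also called with both gates. The largest adjusted p among the genes named by rule was 0.015, for ADM in bladder, and 55.6% to 100% of patients lay above the mean of the others. The median of all genes ranged from -0.23 in colorectal to 0.19 in kidney and from -0.05 to 0.04 after quantile normalisation, and no list described here changed sign. APOE lies on chromosome 19 from 44905754 to 44909393.

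Tumour cells showed the widest differences. SFTPB was higher in lung by 8.57 ± 0.45 (n = 15) and the club-cell protein SCGB1A1 by 7.75 ± 0.50. FXYD2 was higher in kidney by 6.67 ± 0.34 (n = 39) and the chaperone CRYAB by 5.64 ± 0.49. PSCA and S100A2 were higher in bladder by 6.53 ± 0.59 and 6.26 ± 0.80 (n = 13) and KRT14 and KRT5 in head and neck by 6.40 ± 0.60 and 6.17 ± 0.75 (n = 14). CEACAM5 and EPS8L3 were higher in colorectal by 6.37 ± 0.76 and 5.72 ± 0.46 (n = 16). SCGB2A1 and WFDC2 led in gynecologic (5.80 ± 0.44 and 4.73 ± 0.57, n = 30), MFAP5 and COL1A2 in sarcoma (5.32 ± 0.54 and 5.08 ± 0.77, n = 7) and PMEL and S100B in melanoma (5.08 ± 0.54 and 4.62 ± 0.59, n = 14). Kidney tumour cells were higher in 9 of 14 hypoxia and glycolysis genes by both counts (median 1.34 relative to all genes, adjusted p = 0.0142), the HIF targets NDUFA4L2 (5.07 ± 0.53), CA9 (2.75 ± 0.37) and EGLN3 (2.26 ± 0.35) among them. The glucose transporter SLC2A1 was higher in bladder (2.37 ± 0.46) and gynecologic (1.11 ± 0.34), MKI67 in colorectal (1.48 ± 0.42), SNAI2 in head and neck (2.14 ± 0.51) and APOE in melanoma (2.98 ± 0.61).

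Several lists were lower in tumour cells of some types. In colorectal, mesenchymal genes were lower for 3 of 7 over all genes and 6 adjusted over the list alone (median -1.28 relative to all genes, adjusted p = 0.0447), the intermediate filament VIM by -3.99 ± 0.59 and the repressor SNAI2 by -2.82 ± 0.50. Without metastatic specimens 2 of 7 were lower, 6 adjusted over the list alone (adjusted p = 0.00159, and adjusted p = 0.101 with an estimated correlation). In lung 3 of 7 mesenchymal genes were lower, 4 adjusted over the list alone (adjusted p = 0.00185, and adjusted p = 0.109 with an estimated correlation). Fibroblast genes were lower in the colorectal libraries for 6 of 9, 7 adjusted over the list alone (adjusted p = 0.000426, and adjusted p = 0.289 with an estimated correlation). Complement-high macrophage genes were lower there for 6 of 11, 9 adjusted over the list alone (adjusted p = 0.000815, and adjusted p = 0.322 with an estimated correlation). In gynecologic, 3 of 10 genes of MHC class I presentation were lower by both counts (-0.88; adjusted p = 9.41e-06, and adjusted p = 0.237 with an estimated correlation), B2M by -1.32 ± 0.33, the immunoproteasome subunit PSMB9 by -1.60 ± 0.40 and HLA-B by -1.10 ± 0.37 (adjusted p = 0.0575 without metastatic specimens of other types). Genes of immune cells were lower in the same libraries. Complement-high macrophage genes were lower for 3 of 11, 6 adjusted over the list alone (adjusted p = 2.38e-07, and adjusted p = 0.0635 with an estimated correlation). The MHC class II list was lower too (adjusted p = 0.000266, and adjusted p = 0.339 with an estimated correlation), with 1 of 8 genes over all genes and 0 adjusted over the list alone. For T-cell genes, 0 of 7 passed by either count (adjusted p = 0.00111, and adjusted p = 0.354 with an estimated correlation). In lung, 4 of 10 proliferation genes were lower, 5 adjusted over the list alone (-0.94; adjusted p = 0.000192, and adjusted p = 0.322 with an estimated correlation), RRM2 by -2.25 ± 0.50 and TYMS by -1.64 ± 0.42. Beside them 6 of 9 fibroblast genes were lower by both counts (adjusted p = 0.000505, and adjusted p = 0.293 with an estimated correlation). In kidney 4 of 10 proliferation genes were lower by both counts (adjusted p = 0.00434, and adjusted p = 0.396 with an estimated correlation).

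Sarcoma libraries of the tumour gate were higher in genes of several other cell types. All 9 fibroblast genes were higher by both counts (adjusted p = 0.00067). All 7 endothelial genes were higher by both counts (median 2.59 relative to all genes, adjusted p = 0.0271), PECAM1 by 4.03 ± 0.82. So were 8 of 11 complement-high macrophage genes, 9 adjusted over the list alone (3.20, adjusted p = 0.00506), STAB1 by 3.85 ± 0.67 and FOLR2 by 3.57 ± 0.56. The same held for 6 of 7 mesenchymal genes by both counts (2.03, adjusted p = 0.0222), FN1 by 4.29 ± 0.84. MHC class II genes passed for 6 of 8, 8 adjusted over the list alone (2.62; adjusted p = 1.15e-05, and adjusted p = 0.254 with an estimated correlation), HLA-DRB1 by 3.31 ± 0.86. The organ lists passed in their own type by both counts for 7 of 7 lung (5.67, adjusted p = 1.69e-15), 6 of 6 squamous (4.54, 5.03e-08), 8 of 8 melanocyte genes (4.59, 3.56e-09). They passed as well for 7 of 7 colon (3.82, 4.77e-14), 7 of 7 kidney (3.77, 3.2e-08), 4 of 5 urothelial (3.53, 7.4e-07) and 7 of 7 gynecologic genes (3.00, 5.95e-09).

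In tumour cells limma called 7218 of 14536 genes, and 6917 with the title style as a term. Without the EPCAM-gated libraries 4637 were called, of which 4550 were also called with both gates. The largest adjusted p among the genes named by rule was 0.0139, for SLC2A1 in gynecologic, and 64.3% to 100% of patients lay above the mean of the others. The median of all genes ranged from -0.30 in colorectal to 0.24 in sarcoma and from -0.08 to 0.01 after quantile normalisation. No list described here changed sign. CA9 lies on chromosome 9 from 35673856 to 35681159 and B2M on chromosome 15 from 44711487 to 44718877.

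**Figure D2:**
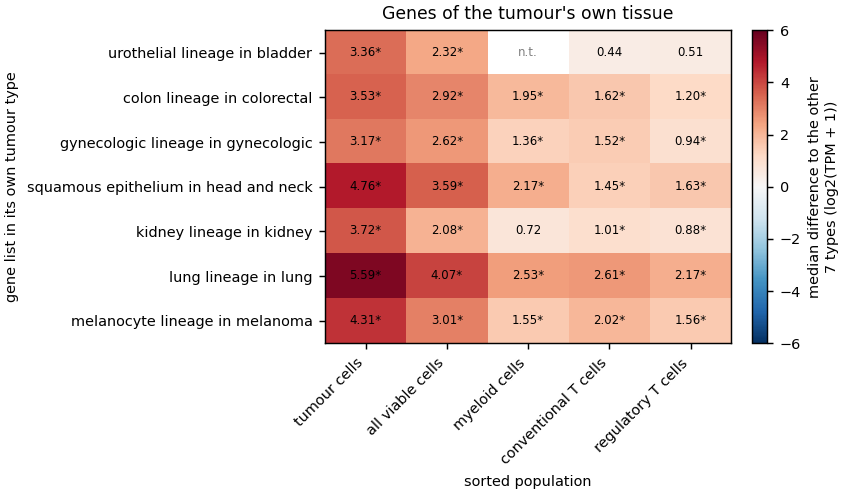
Median difference to the other 7 tumour types (log2(TPM + 1), not relative to all genes) of 7 organ gene lists, each in its own tumour type (rows), in 5 sorted populations (columns); an asterisk marks an adjusted p under 0.05 with an estimated correlation and n.t. fewer than 3 tested members. The kidney list stands at 3.72 in tumour cells, 2.08 in viable cells, 0.72 in myeloid cells, 1.01 in conventional and 0.88 in regulatory T cells.

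Regulatory and conventional T cells of the same patient were compared in 134 pairs. The chemokine receptor CCR8 was higher in regulatory T cells by 4.94 ± 0.18 log2 (SE), at 7.92 against 2.99, in 130 of 134 pairs. CD177 (4.63 ± 0.17, 129 pairs), IL2RA (4.48 ± 0.14, 132 pairs), the chemokine CCL22 (4.45 ± 0.20, 125 pairs) followed. So did the interleukin-1 receptors IL1R2 (4.44 ± 0.16, 130 pairs) and IL1R1 (3.74 ± 0.11, 133 pairs), FOXP3 (4.31 ± 0.14, 131 pairs), FANK1 (4.05 ± 0.16, 128 pairs), LAIR2 (3.06 ± 0.17, 122 pairs) and TNFRSF18 (3.05 ± 0.14, 131 pairs). The activating receptor KLRK1 was lower by -5.91 ± 0.17 and higher in only 2 pairs. Also lower were CD8A (-5.29 ± 0.17), the granzymes GZMK (-4.86 ± 0.17), GZMH (-4.71 ± 0.18) and GZMA (-4.30 ± 0.15), NKG7 (-4.78 ± 0.20), CD8B (-4.59 ± 0.14), CCL5 (-4.51 ± 0.13), CRTAM (-4.35 ± 0.15) and AUTS2 (-4.21 ± 0.20), none of them higher in more than 5 pairs. The gates themselves, CD4 and CD25, set part of these differences.

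By list, 15 of 15 regulatory T-cell genes were higher (median 2.67 relative to all genes) and 13 of 14 cytotoxic genes lower (-3.58), each with an adjusted p of 4.74e-06. Of 11 exhaustion and chronic activation genes 3 were lower (CXCL13 by -1.99) and 6 higher (1.47; adjusted p = 0.0049, and adjusted p = 0.299 with an estimated correlation). These 6, such as LAYN (2.65 ± 0.14), are also in the regulatory list. Of 9 naive and central memory genes 4 were lower and 1 higher (-0.34; adjusted p = 0.0284, and adjusted p = 0.367 with an estimated correlation), TCF7 by -2.15 ± 0.12, the egress receptor S1PR1 by -1.72 ± 0.13 and KLF2 by -1.10 ± 0.11. No proliferation gene of 8 reached a difference of 1 log2 (0.57; adjusted p = 0.0103, and adjusted p = 0.299 with an estimated correlation), RRM2 standing at 0.99 ± 0.13. Nor did any of 14 immediate-early and heat-shock genes (-0.26; adjusted p = 0.000252, and adjusted p = 0.13 with an estimated correlation), FOS standing at -0.94 ± 0.09. Adjusted over the list alone, all these counts were the same.

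With the patient as a block limma called 477 of 8240 genes, of which 259 were lower. With the number of detected genes as a covariate the split was 282 higher and 229 lower, and without the filter on low values 744 genes were called. The levels of both sorts come from separately made tables. Over 127 pairs of the 8 types the difference varied between types for 52 of 8240 genes. CCR8 lies on chromosome 3 from 39329706 to 39333511. FOXP3 lies on chromosome X from 49250436 to 49264826 and KLRK1 on chromosome 12 from 10372353 to 10391874.

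**Figure D3:**
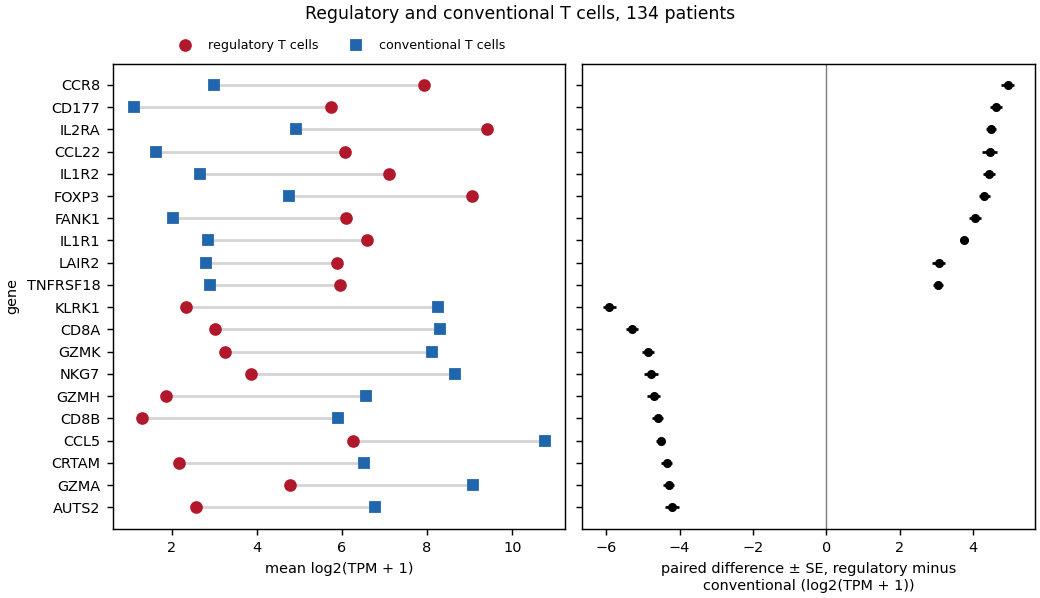
Left, mean log2(TPM + 1) of 20 genes (rows) in regulatory (circles) and conventional (squares) T cells of 134 patients; right, their paired difference, regulatory minus conventional, with the SE as bars. Differences run from -5.91 for KLRK1 to 4.94 for CCR8.

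Metastatic and primary melanoma differed in viable cells, with 13 metastatic and 16 primary patients. B-cell genes were higher in metastatic specimens: the IgM receptor FCMR by 3.66 ± 0.72 (SE, adjusted p = 0.00342) and MS4A1, the CD20 gene, by 3.44 ± 0.93 (0.0195). So were CD79A by 3.34 ± 0.84 and the B-cell transcription factor PAX5 by 3.19 ± 0.70. NELL2, which is not in the B-cell list, was higher by 3.30 ± 0.62. Melanocyte genes were lower: EDNRB by -4.72 ± 0.93, the pigment enzyme TYRP1 by -4.72 ± 1.22, SERPINE2 by -4.37 ± 0.83, the melanosome linker MLPH by -4.25 ± 0.72 and the lineage transcription factor MITF by -4.18 ± 0.88. By list, 5 of 7 T-cell genes were higher, 7 adjusted over the list alone (median 2.17 relative to all genes), CD3E by 2.67 ± 0.63, with 3 of 4 B-cell genes, 4 adjusted over the list alone (3.36). Of 7 melanocyte genes 6 were lower, 7 adjusted over the list alone (-3.82). At the preset correlation the adjusted p was 5.62e-07 for T cells and melanocytes and 5.13e-05 for B cells, and each had an adjusted p = 0.15 with an estimated correlation.

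Genes of MHC class I presentation were higher for 2 of 10, 5 adjusted over the list alone (1.06; adjusted p = 5.13e-05, and adjusted p = 0.26 with an estimated correlation), NLRC5 by 1.85 ± 0.48. Monocyte genes were lower for 2 of 8, 6 adjusted over the list alone (-1.87; adjusted p = 0.000697, and adjusted p = 0.288 with an estimated correlation), S100A8 by -2.71 ± 0.75. SPP1-type macrophage genes were lower for 3 of 6, 4 adjusted over the list alone (-1.94; adjusted p = 0.0021, and adjusted p = 0.231 with an estimated correlation), SPP1 by -3.45 ± 1.03. Of 8898 genes limma called 667, 309 higher and 358 lower. The count was 360 (270 higher, 90 lower) with the number of detected genes as a covariate, 393 with the title style as a term, and 1322 without the libraries with the fewest detected genes, which left 9 and 14 patients. Rescaling TPM over the analysed genes moved the split to 252 higher and 635 lower and the median of all genes tested from -0.09 to -0.30, and no list described changed sign. MS4A1 lies on chromosome 11 from 60455752 to 60470760, FCMR on chromosome 1 from 206904386 to 206923247.

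In conventional T cells (8 metastatic, 14 primary) 6 of 9008 genes passed in limma: RASGRP2 (2.27 ± 0.40, adjusted p = 0.0164), YPEL5 (1.67 ± 0.30), SORL1 (1.85 ± 0.38) and PABPC4 (1.26 ± 0.26) higher, and the galectin LGALS1 (-2.99 ± 0.54) and CD63 (-2.75 ± 0.52) lower in metastatic melanoma. None passed with the title style as a term, and 968 had an unadjusted p under 0.05. Naive and central memory genes were higher as a list (median 1.73 relative to all genes, adjusted p = 0.0259), with none of 9 over all genes and 9 of 9 adjusted over the list alone; LEF1 stood at 2.65 ± 0.57. Cytotoxic genes were lower as a list (-1.76; adjusted p = 2.51e-10, and adjusted p = 0.0924 with an estimated correlation), with none of 14 over all genes and 7 adjusted over the list alone, GZMA standing at -2.29 ± 0.53. RASGRP2 lies on chromosome 11 from 64726911 to 64745456 and CD63 on chromosome 12 from 55725323 to 55729707.

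In myeloid cells (6 metastatic, 12 primary) 4 of 8584 genes passed in limma: the cytotoxic granule gene GNLY (4.22 ± 0.77, adjusted p = 0.0398), the cytokine receptor IL2RB (4.02 ± 0.67) and SLC38A1 (3.48 ± 0.64) higher and SDC2 (-3.84 ± 0.72) lower. Beside GNLY and IL2RB, which lymphocytes make, the T-cell genes CD2 and CD5 stood at 1.41 ± 0.62 and 0.90 ± 0.85 and did not pass. With an estimated correlation SPP1-type macrophage genes (median -3.02 relative to all genes, adjusted p = 0.00793) and inflammatory cytokine genes (-3.07, adjusted p = 0.0299) were lower as lists, with none over all genes and 6 of 8 and 4 of 8 adjusted over the list alone, TREM2 standing at -2.75 ± 0.76 and IL1A at -3.86 ± 1.12. The title style as a term left 2 genes, no gene passed at a pseudocount of 0.1, and 981 had an unadjusted p under 0.05. The median of all genes was 0.36 and fell to 0.03 under quantile normalisation, which turned no list described.

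Scores of the same patient in different sorts were related across patients within tumour types. The interferon-gamma-inducible score of myeloid cells rose with the exhaustion score of conventional T cells (Pearson r = 0.544, n = 151, permutation p = 1e-05, the smallest that 100000 shuffles give; adjusted p = 2.5e-05; Spearman rho = 0.552, adjusted p = 2.5e-05). Within the 3 title styles r was 0.395 (n = 48), 0.56 (n = 63) and 0.613 (n = 40). MHC class I presentation in tumour cells rose with the T-cell score of viable cells (r = 0.414, n = 148, p = 1e-05, adjusted p = 2.5e-05; rho = 0.422, adjusted p = 2.5e-05), at 0.399, 0.418 and 0.347 within styles. The regulatory score of regulatory T cells rose with the exhaustion score of conventional T cells (r = 0.365, n = 127, p = 0.0001, adjusted p = 0.000167; rho = 0.288, adjusted p = 0.00208). Within styles r was 0.346 (p = 0.0555), 0.366 and 0.51. Of the 11 exhaustion genes 6 are in both lists, and the relation was not tested without them. The T-cell score of viable cells rose with the exhaustion score (r = 0.265, n = 182, p = 0.00072, adjusted p = 0.0009; rho = 0.238, adjusted p = 0.00239), but within styles r was -0.181 (n = 64, p = 0.214), 0.415 (n = 74) and 0.553 (n = 44), so this relation did not hold in the first style. Hypoxia in tumour cells and the SPP1-type score of myeloid cells were not related past the threshold (r = 0.118, n = 122, p = 0.188; rho = 0.078, adjusted p = 0.404), at 0.191, 0.064 and 0.078 within styles. Without the 2 patients farthest from the median r was 0.545, 0.411, 0.378, 0.216 and 0.132 in this order.

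**Figure D4:**
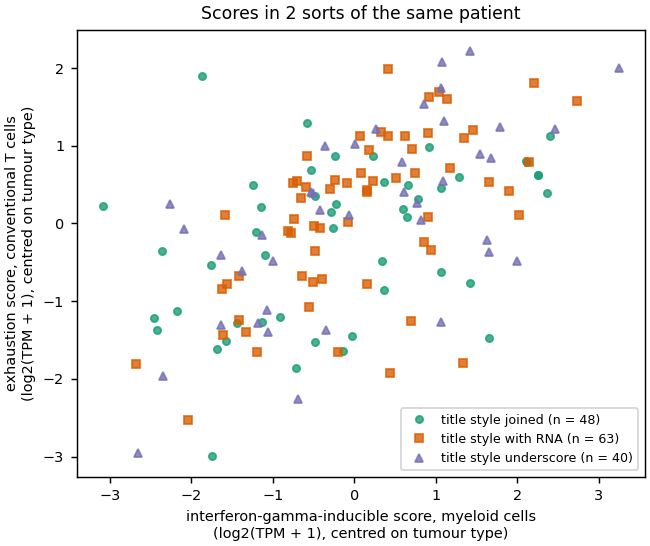
Each point is a patient: the interferon-gamma-inducible score of myeloid cells (x) against the exhaustion score of conventional T cells (y), both in log2(TPM + 1) and centred on tumour type, with symbols for the 3 title styles (n = 48, 63 and 40). The points rise together, with r = 0.544 over all 151 patients.

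Single myeloid cells of head and neck tumours (3 donors) and melanoma lesions (5 donors) were compared by class. Mast-like cells made up 4.46% ± 3.29 of cells in head and neck (SD, n = 3) and 0.39% ± 0.36 in melanoma (SD, n = 5), a difference of 4.07 points with a two-sided exact permutation p of 0.0179, the smallest that 56 splits allow, and an adjusted p of 0.214. LAMP3 dendritic-like cells were at 2.70% ± 1.45 and 1.23% ± 0.78 (exact p = 0.0893, adjusted p = 0.536). Macrophage-like cells stood at 23.7% ± 16.7 and 23.1% ± 12.96, monocyte-like cells at 16.1% ± 9.51 and 17.6% ± 9.04, type 2 dendritic-like cells at 8.30% ± 3.13 and 9.81% ± 9.16, and plasmacytoid dendritic-like cells at 16.6% ± 21.04 and 4.86% ± 4.62. T or NK-like cells, which the gate was set to leave out, made up 3.07% ± 3.16 and 14.3% ± 19.2, and unnamed clusters 14.8% ± 6.24 and 13.2% ± 4.52. None of 12 classes passed after adjustment, and with 56 splits 1 class alone could not. Melanocyte-like cells rest on a cluster of 329 cells led by APOD, SERPINE2 and CALD1, of which 63 came from head and neck and 50 from kidney libraries. The unfiltered barcodes of the head and neck matrices and the filtered ones of melanoma, and median UMIs per cell of 1994 to 6797 in the libraries compared, stand beside these shares.

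**Figure D5:**
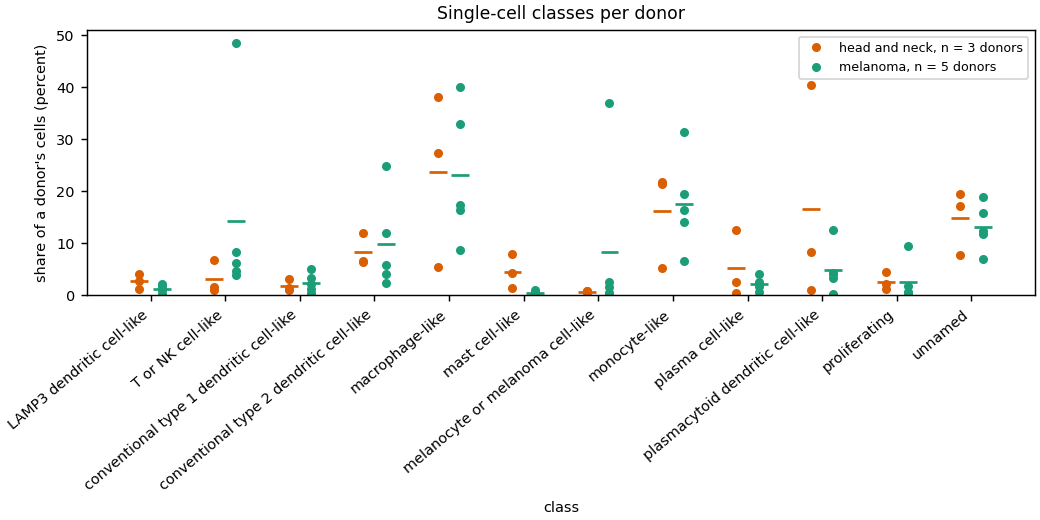
Share of cells in each class (percent) for 3 head and neck and 5 melanoma donors; points are donors and bars their means. Mast-like cells average 4.46% in head and neck and 0.39% in melanoma.

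Within monocyte-like and macrophage-like cells, edgeR called none of 10651 genes between head and neck and melanoma donors (3 against 5). The smallest adjusted p was 0.098, and 828 genes had an unadjusted p under 0.05. DESeq2 called 46, and edgeR called 11 without head and neck donor 3 and 2 without melanoma donor 3. Interferon-gamma-inducible genes were at a median of -2.07 log2 in head and neck relative to melanoma, with none of 9 over all genes and 3 adjusted over the list alone; CXCL11 stood at -3.81 ± 1.15, and GBP4 at 18.5 CPM of summed UMIs in head and neck against 54.1 in melanoma. The list was called at the preset correlation (adjusted p = 0.000347, and adjusted p = 0.615 with an estimated correlation). Inflammatory cytokine genes were at 0.92 (adjusted p = 5.07e-05, and adjusted p = 0.615 with an estimated correlation), none of 8 over all genes or adjusted over the list alone, TNF standing at 1.79 ± 0.72. Immediate-early and heat-shock genes were at 0.50 (adjusted p = 0.00131, and adjusted p = 0.499 with an estimated correlation), none of 14 over all genes and 1 adjusted over the list alone, JUN standing at 1.61 ± 0.43. Over cells pooled across donors the largest macrophage cluster was led by SEPP1, APOE and FOLR2 in head and neck (33.1% of the class) and by CCL2, SPP1 and MARCO in melanoma (31.7%). Per donor the former held 21.3% to 40.6% of macrophage-like cells in head and neck and 24.8% to 34.8% in melanoma, and the latter 21.4% to 43.3% and 20.3% to 38.1%. The donors of both tumours overlapped, and no difference was tested.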

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

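The test of a lower share of tumour cells in metastatic melanoma was chosen after the result was seen, as was the test of tumour types on the difference between T-cell sorts. The detected genes and title style for the relation between myeloid and T-cell scores were alternatives fixed in advance, and were used to test an explanation only after their values were seen.

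In each of 41 groups of 4 to 10 samples the highest and lowest values were set against the rest by Dixon's ratio of gap to range, and 4 passed the 95% critical value, where chance gives about 1 in 20. CD63 in conventional T cells of metastatic melanoma had 1 library at 8.49 log2(TPM + 1) with the next at 6.25, a ratio of 0.567 (n = 8). Among the 5 melanoma donors with single cells, T or NK-like cells made up 48.6% of cells in 1 donor and 8.23% in the next (ratio 0.902), and proliferating cells 9.47% and 1.82% (0.847). Melanocyte or melanoma-like cells made up 37.04% of cells in 1 donor, which had only 243 cells, and 2.54% in the next (0.94). For none (0) of the 20 genes named between regulatory and conventional T cells did the difference vary over tumour types at an adjusted p under 0.05.

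Genes of the tumour's own tissue were higher in conventional T cells of that type, although the T-cell gate would remove tumour cells. Across the genes higher in tumour cells, the excess in T cells rose with the excess in tumour cells, with a median Spearman rho of 0.48 over the 8 types (0.269 to 0.669; genes are not independent replicates). The T-cell excess was 0.84% to 14.3% of that in tumour cells, so carried tumour RNA may be its source. The number of detected genes as a covariate left 95.7% of 23 called genes called (median 2.01 before and 2.01 after) and the title style 100% (2.01 and 2.06), which argues against both as the whole cause. The type 17 genes of colorectal T cells go against carried tumour RNA, since 7 of 7 had a lower mean TPM in colorectal tumour cells than in T cells, IL17A at 0.03 against 19.8 and IL26 at 0 against 10.0, and a difference between tumour types stays open for them as an untested hypothesis. 

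In viable cells of metastatic melanoma lymphocyte genes were higher and melanocyte genes lower. A lower share of tumour cells alone would raise T-cell and monocyte scores alike, but they moved apart by 3.944 log2 (SE 0.943, permutation p = 0.00039), T cells by 2.14 and monocytes by -1.80. With the title style as a term 92.9% of 14 called genes stayed called (median size 3.39 before and 3.37 after), while with detected genes as a covariate 64.3% did (3.39 and 3.10, all 14 with their sign), so the latter cannot be told apart from stage for the genes whose call ended. Of 12 lymph node genes 9 were higher adjusted over the list alone, CD22 at 294 against 88.5 mean TPM and LTB at 194 against 45.4, but not FDCSP, CCL19 or CCL21. Lymph node tissue in the metastatic specimens may be the source, though lymphoid tissue formed within tumours would bring the same genes the viable-cell gate removes neither, and an effect of stage itself stays open, untested.

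The interferon-gamma-inducible score of myeloid cells rose with the exhaustion score of conventional T cells of the same patient. Given the detected genes of both libraries r was 0.534, and the lowest r within a title style was 0.395, which argues against both as the whole cause. Given the T-cell score of the myeloid library and the MHC class II and complement-high scores of the T-cell library, r was 0.389 (bootstrap interval 0.25 to 0.523, n = 151) against 0.544 without them, so RNA carried between the sorts cannot be told apart from a relation between the cells. No biological explanation was tested.

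Patients were regrouped at random into groups of the same sizes, 100 for each comparison with the real one included. For 8 results only the real grouping gave a count as large as the real one. Such counts were thus rare under random grouping, at 1 of 100 each, the smallest share that 100 regroupings can give. The real count and the highest other were 6519 and 12 in viable cells, 2453 and 3 in conventional T cells, 1156 and 20 in regulatory T cells, 3494 and 73 in myeloid cells. They were 7218 and 4 in tumour cells, 477 and 0 between the T-cell sorts, 667 and 314 between melanoma stages in viable cells and 4 and 2 in myeloid cells. The myeloid stage count of 4 became 0 at a pseudocount of 0.1, so chance stays open there. For melanoma stage in conventional T cells 2 of 100 gave as many as the real 6, the highest other at 8. In single monocyte-like and macrophage-like cells the real count was 0, so all 56 splits had to reach it (the highest other gave 6) and the count of splits decides nothing about chance.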

How the results depend on the processing

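The settings that leave out near-identical libraries, metastatic specimens or each sarcoma patient, rescale TPM and change the integration, naming or doublet threshold of single cells were chosen after seeing the data. Of 126 values of main results under alternatives fixed in advance 100 stayed on their side of the threshold or within 1.5 times the count, as did 39 of 40 under settings added later. For 461 named gene results, 4734 of 4988 values kept direction and side of the threshold, 190 lost the call, 64 gained one and 0 turned direction, and 346 results never changed. Without metastatic specimens 20 lost the call and 2 gained it, most of them in melanoma, while the counts across types stayed within 1.5 times (893 against 1156 in regulatory T cells). Across types, 2111 genes were called in myeloid cells with the CD11b gate alone (3494 with both gates) and 4637 in tumour cells without the EPCAM gate (7218). These fits hold fewer libraries. Between the T-cell sorts no filter on low values gave 744 genes against 477, over more genes tested. Leaving out each sarcoma patient in turn gave 1061 to 1215 genes across types in regulatory T cells, but ended calls of single named genes of sarcoma (2 without patient 1, 5 without 2, 3 without 4 and 5 without 5) and gave 1 without patient 3.

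Between melanoma stages in viable cells the count of 667 became 360 with detected genes as a covariate, 1322 without the libraries with the fewest detected genes, 393 with the title style as a term and 1071 with each library as a replicate. In conventional T cells the count of 6 became 46, 114, 0 and 27 under the same settings and 1 with no filter on low values. In myeloid cells the count of 4 became 11, 12, 2 and 13 under them, 0 at a pseudocount of 0.1, 1 with no filter and 1 after rescaling TPM. The cause was not tested.

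Of the 5 relations 4 passed over all patients and 2 within the joined title style. There the regulatory and exhaustion scores had r = 0.346 (adjusted p = 0.0925), and the T-cell and exhaustion scores turned to r = -0.181 (adjusted p = 0.265). In single monocyte-like and macrophage-like cells the edgeR count of 0 became 18 with cells of at least 500 UMIs and 300 genes. It became 50 with no low-count filter, DESeq2 gave 46, and leaving out each donor in turn gave 0 to 11. No class share passed when any donor was left out. Yet 1 class alone could not pass over 12 classes even with all donors (smallest adjusted p = 0.214), so this says nothing about stability. No cause was tested.

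Patients pair the T-cell sorts. The fit with no replicate block, which ignores the pairing, also called 477 genes, and the block changed no other call named here. No paired analysis was possible for tumour type, melanoma stage or single cells because no patient has libraries in several of the groups compared. The bulk depth is unknown, so no count-based limit of detection can be given, and single-cell shares of the donor with 243 cells rest on few cells.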

Other observations

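The single-cell values given here were not tested.

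The lymph node library of a melanoma patient and the kidney tumour library are single libraries, so they have no replicate check, and the exact binomial intervals cover counting error only. Plasmacytoid dendritic-like cells made up 41.99% of 4275 cells in the lymph node (95% interval 40.5% to 43.5%) and 0.01% of 11742 cells in the kidney tumour. Macrophage-like cells made up 17.1% in the lymph node. In the kidney tumour 31.8% were monocyte-like (30.9% to 32.6%), 28.8% macrophage-like (27.9% to 29.6%) and 33.2% in unnamed clusters (32.3% to 34.03%).

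Among the clusters that no marker list named, the largest, of 2639 cells, was led by the inflammatory genes CCL20, TNFAIP6, IL1A, PTGS2 and CXCL8. Clusters of 1895 and 584 cells were led by the heat-shock gene HSPA6, 1 of 1306 cells by CDKN1C and HES4, 1 of 950 cells by LTB and S100B, and 1 of 477 cells by SPINK2, KLRB1 and XCL1. A named macrophage-like cluster was led by JUN, HSPA1B and HSPA6, and another by CXCL10, CXCL9 and GBP1. Plasma-like clusters had median UMIs 2.35 and 3.13 times those of their libraries, which doublets or large cells would both give and which was not tested.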
